A study of Mus musculus with 5 samples.

How the data were processed

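The counts per barcode deposited by the authors came from 10x Chromium 3' version 2 libraries sequenced on a NextSeq 500. Per the submitters' processing notes they were made with Cell Ranger against mm10 with a tdTomato sequence added, and later steps used Seurat. No versions are given for either program. The cell filter applied before deposit is not given in the sources used here. The deposited counts were whole numbers over 28001 features and were read as UMI counts without any further scaling. The bulk library was deposited by the authors as FPKM values, and its sequencing depth is unknown. That file held 22058 entries under 21577 names. The 726 entries of the 245 names that occurred more than once were left out. It was used for levels alone, since FPKM values of 1 pool carry no spread between pools.

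Cells with fewer than 300 genes or more than 10% mitochondrial RNA were left out. Doublets were called in each library by Scrublet, run through scanpy 1.11.5 with an expected rate of 0.05, and 25 of 3503 barcodes (0.718%) were removed. After these filters 3455 cells remained. The authors' cell names were not used. Cell classes were rebuilt from 2000 variable genes, with tdTomato, mitochondrial and ribosomal genes left out. Counts were scaled to 10000 per cell, and 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1.0 gave 24 clusters. Clusters were named from 20 marker lists, and 3 clusters stayed unnamed. The stromal-like class joined pericyte-like, smooth muscle-like and fibroblast-like clusters, and the mural-like class joined the pericyte-like and smooth muscle-like clusters. Names of classes end in "-like" because they rest on RNA alone. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 was used, with seed 1.

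UMIs were summed per library and class, and classes with fewer than 20 cells in a library were not tested. Genes were filtered by filterByExpr and tested with edgeR 4.0.16 quasi-likelihood F tests after TMM scaling, in R 4.3.3. Adjusted p values are Benjamini-Hochberg values over all tested genes, and a gene was called at an adjusted p below 0.05. Each p value measures the spread between pools of 4 mice, of which each group had 2, except in the microglia-like fit, where the 1 control library adds no spread. It does not measure the spread between mice. DESeq2 1.42.0 and its size factors were alternatives. The difference of the stroke effect between fibroblast-like and pericyte-like cells was tested by edgeR on 8 class sums with a term for the library, leaving 2 residual degrees of freedom.

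Genes named from the tests were fixed by a rule written before the data were examined. Leading genes of clusters, genes of the bulk pool and levels in smooth muscle-like cells were named outside this rule. Fixed genes came first: tdTomato, Hic1, Pdgfrb, Pdgfra, Cspg4, Rgs5, Kcnj8, Abcc9, Acta2, Col1a1, Col4a1, Vtn and Mki67 in stromal classes, and P2ry12, Tmem119, Cx3cr1, Apoe, Spp1, Lpl and Mki67 in microglia-like cells. Up to 8 rises and 8 falls with the largest log2 fold changes were added. These had an adjusted p below 0.05, at least 50 CPM on average in 1 group and library values that did not overlap between groups, and predicted genes were left out. The 4 members with the smallest p of each list came last. For 2 genes that the rule names, the results are not reported here. Where a group had 0 UMIs of a gene, the ratio was taken against a floor of 3 counts over that group and is given as "at least". Where a group had 1 to 3 UMIs, the ratio of sums is given with its 95% counting interval. That interval covers the counting of UMIs alone and not the spread between pools, so it does not replace the adjusted p.

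The 27 lists of genes were tested with camera (limma 3.58.1) at its preset correlation of 0.01, again with a correlation estimated from the libraries, and with the rotation test fry. Lists with fewer than 5 tested members got no test. In fry the directional p asks whether the members move on balance one way, and the other p asks for change in either direction. The 20 marker lists were tested in the same manner and adjusted apart.

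Shares were compared over libraries by exact permutation. With 2 pools against 2 the smallest possible two-sided p is 0.333. Intervals of shares are exact 95% binomial intervals, and a share of 0 has the limit 3 over the number of cells. A cell was counted as cycling with UMIs of at least 2 of 10 cell cycle genes after each cell was thinned to 1500 UMIs, and cells below that depth were left out of this count. Beside this, the unthinned shares are given. For the cycling cells of stroke the class was also given cell by cell, as the pericyte, smooth muscle or fibroblast marker list with the highest mean z score within the library.

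The fits were tested on simulated data with 200 genes changed among otherwise unchanged ones, 50 at each fold of 2, 4, 16 and 64, at the spread seen between the pools. In stromal-like cells 0, 18, 86 and 80% were recovered, with 8 false among 100 calls. In pericyte-like cells 4, 32, 80 and 78% were recovered (15 false of 112). In fibroblast-like cells the values were 0, 20, 78 and 84% (9 of 100), and in mural-like cells 0, 10, 86 and 84% (7 of 97). For microglia-like cells they were 4, 12, 74 and 82% (18 of 104). For the difference between classes they were 14, 58, 84 and 94% (7 of 132). A 2-fold change was thus rarely called in any comparison, and no call is no evidence of an unchanged gene.

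Alternatives changed 1 setting at a time: DESeq2 size factors, no filter on genes, the DESeq2 test, each library left out, no doublet removal, at least 1000 UMIs per cell, no mitochondrial limit, Leiden resolutions of 0.5 and 2.0, equal numbers of cells per library, and removal of cells with more than 1 percent of their UMIs from a list of abundant RNAs of the other sorted population. Chosen after the data were seen were the fits without a cluster of control cells alone, without a cluster with Ifit genes among its leading genes, with equal cells per class and library, the mural-like class, the microglia-like fit of 1 control against 2 stroke libraries, and the lists in pericyte-like, fibroblast-like, mural-like and microglia-like cells. Macrophage-like cells, from clusters named as monocytes or border macrophages, numbered 5, 0, 18 and 13 at resolution 1.0 and 10, 0, 76 and 48 at resolution 0.5. They were not tested, since both controls stayed under 20 cells at every setting. The Leiden resolutions of 0.5 and 2.0 gave the same stromal-like and fibroblast-like sums as the main fit, so they could not change calls there. Removal by RNA of the other population kept 239, 228, 583 and 1188 stromal-like cells of 239, 228, 584 and 1189. Counts of alternatives in which a gene stayed called include these settings. Reads were not analysed here.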

Results

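Cells that carried the tdTomato label after Hic1-driven recombination were sorted from mouse brain, and 4 single-cell libraries and 1 bulk library were available. Control library 1 and control library 2 came from hemispheres contralateral to a photothrombotic stroke, and stroke library 1 and stroke library 2 came from the dissected ischaemic area. Each was a pool of 4 mice, male and female, aged 2 to 5 months, and day 7 after stroke is stated for stroke 1 alone. CD45-negative tdTomato-positive cells were sorted 2 times and mixed with equal numbers of CD45-positive tdTomato-negative carrier cells. The libraries held 554, 252, 961 and 1736 barcodes (control 1, control 2, stroke 1, stroke 2), with 1383304, 1116488, 6194350 and 16293335 UMIs. Median depth was 2248.5, 3420.5, 5842 and 8886.5 UMIs per barcode, so stroke cells were deeper, and a minimum of 50000 reads per cell is stated for all. The filters kept 544, 251, 951 and 1709 cells. Tissue and injury differed together between the groups, so an effect of dissecting a smaller region was not separated from an effect of stroke.

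The bulk pool showed what the sorted Hic1-lineage population of uninjured tissue expressed, as levels in FPKM without a test. Vtn, which encodes the adhesion protein vitronectin, was the most abundant transcript at 12566 FPKM, followed among stromal genes by Igfbp7 (4222) and Mgp (4076). The pericyte genes Rgs5 (1476), Kcnj8 (982) and Pdgfrb (835), the contractile gene Myl9 (2219) and the fibroblast genes Apod (2136) and Dcn (938) were all high, and Hic1 itself stood at 85.8. Median levels of marker lists were 549 for pericytes, 192 for fibroblasts and 67.2 for smooth muscle, against 7.52 for endothelium, 6.22 for microglia, 0.532 for astrocytes, 0.245 for neurons and 1.53 for oligodendrocytes. Choroid plexus markers had a median of 9.94, with the transthyretin gene Ttr at 3788, and the haemoglobin gene Beta-s stood at 4251. Some genes with few or no UMIs in control but high levels in stroke cells were low here: Thy1 5.92, H19 1.51, Vcan 0.510 and Mmp3 0.001, the smallest value above 0. Other genes that were higher in stroke cells were not low, among them Col1a1 (256), Col3a1 (212) and Col4a1 (337). The Spearman correlation across 19341 genes with the stromal-like sums of control 1 and control 2 was 0.889 and 0.918.

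Which cells were present in each library? Stromal-like cells numbered 239, 228, 584 and 1189, made up of pericyte-like (124, 134, 24 and 366), smooth muscle-like (59, 48, 326 and 319) and fibroblast-like cells (56, 46, 234 and 504). Immune-lineage cells numbered 305, 0, 367 and 514, of which 263, 0, 78 and 393 were microglia-like. The share of cells in unnamed clusters was 1.47, 9.16, 15.1 and 3.75%. In 2 of the unnamed clusters macrophage genes were among the leading genes (Spp1 and Pf4 with 3, 0, 86 and 23 cells, Lyz2 and Ms4a7 with 5, 0, 58 and 35), and the other was led by Slc47a1 and Nov (0, 23, 0 and 6 cells).

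The reporter was found in nearly all stromal-like cells, with a tdTomato UMI in 90.0, 98.7, 98.8 and 100% of them at median depths of 1733, 3272, 7284 and 8878 UMIs. In immune-lineage cells, which were sorted as reporter-negative, the share was 11.5, 14.4 and 62.6% in control 1, stroke 1 and stroke 2 at median depths of 2557, 3993 and 8896 UMIs. As a level, however, tdTomato stood at 43.7, 35.7 and 129 CPM in immune-lineage cells against 1629, 3578, 1374 and 4039 CPM in stromal-like cells.

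Did the make-up of the stromal-like cells differ after stroke? Pericyte-like cells made up 51.9% (95% interval 45.4 to 58.4) and 58.8% (52.1 to 65.2) of the control stromal-like cells, and 4.11% (2.65 to 6.05) and 30.8% (28.2 to 33.5) of the stroke ones. Fibroblast-like cells made up 23.4 and 20.2% in control against 40.1 and 42.4% in stroke, and smooth muscle-like cells 24.7 and 21.1% against 55.8 and 26.8%. By exact permutation over the 4 libraries each p was 0.333, the smallest possible value with 2 pools per group, for differences of -37.88 points (pericyte-like), 19.43 points (fibroblast-like) and 18.46 points (smooth muscle-like). The pericyte-like difference was -41.33 points without control 1, -34.44 without control 2, -24.55 without stroke 1 and -51.22 without stroke 2. The smooth muscle-like difference was 20.27 points without control 1, 16.64 without control 2, 3.96 without stroke 1 and 32.95 without stroke 2, and the fibroblast-like one lay between 17.8 and 21.05 points. Stromal-like barcodes of stroke 2 began at 2292 UMIs, and with all libraries held to that minimum the pericyte-like shares were 23.4% (13.8 to 35.7, 64 stromal-like cells left), 59.2, 1.62 and 30.8%. Pericyte-like and smooth muscle-like cells together made up 76.6, 79.8, 59.9 and 57.6% of stromal-like cells. Defining genes such as Vtn differed in level between the groups in smooth muscle-like cells, so the separate shares depend on how clusters were named. With the class given cell by cell, 173 of 582 and 416 of 1189 stroke cells scored highest for the pericyte marker list. The markers were scaled within each stroke library, so these scores are relative. Control libraries were not scored in this way, and the counts do not estimate a share of pericytes. These are shares after a sort of tdTomato-positive cells at the depths given above, and they do not count cells in the tissue.

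**Figure D1:**
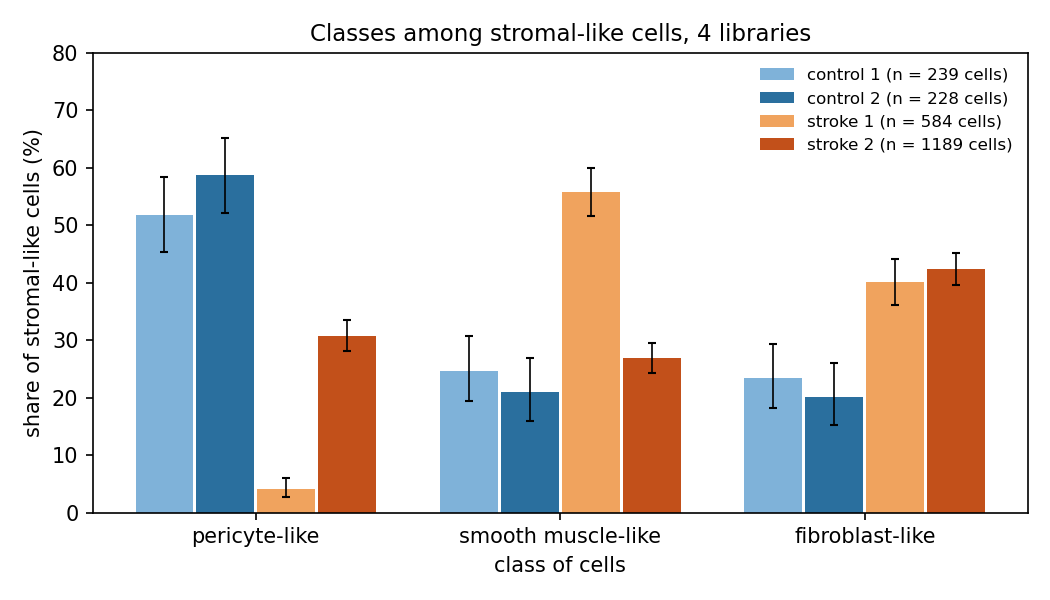
Share of stromal-like cells (%, vertical axis) that were pericyte-like, smooth muscle-like or fibroblast-like in each of the 4 libraries, with bars for shares and lines for exact 95% intervals (239, 228, 584 and 1189 cells). The pericyte-like bar is lowest in stroke 1, at 4.11%.

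Which clusters made up each class? Pericyte-like cells of control 1, control 2, stroke 1 and stroke 2 lay in a cluster led by Car4 and Slc6a20a (3, 127, 2 and 265 cells), in one led by Atp13a5 and Pdzd2 (120, 7, 20 and 1 cells) and in one led by Sfrp2 and Nts (1, 0, 2 and 100 cells). The last had the interferon-induced genes Ifit3, Ifit1 and Iigp1 also among its leading genes. Smooth muscle-like cells of control lay in a cluster with Lmcd1 and Tagln among its leading genes (59 and 48 cells, with 10 and 15 stroke cells). Those of stroke 1 lay mostly in a cluster led by Olfr558, Rgs5, Acta2 and Myh11 (282 cells) and those of stroke 2 in a cluster led by Agt and Rgs16 (284 cells). Fibroblast-like cells of control lay mostly in clusters led by Ptgds and Slc6a13 (27 and 18 cells, with 3 and 19 stroke cells) and by Coch and Tcf21 (25 and 26 cells, with 0 stroke cells). Those of stroke lay mostly in clusters led by Nrk and Col7a1 (136 cells in stroke 1), by Ramp2 and Clec3b (329 cells in stroke 2) and by Clec11a and Prss12 (46 and 143 cells), the last with Mmp13, H19 and Mmp3 also among its leading genes. A further fibroblast-like cluster, led by Ptgds and Nnat with Slc6a13 also among its leading genes, held 3, 2, 49 and 9 cells.

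Which genes differed in stromal-like cells? Collagen genes such as Col1a1 and Col3a1 rose after stroke, and Tcf21, Coch and Trf fell. The large chondroitin sulphate proteoglycan gene Vcan, the stromelysin gene Mmp3 and the glycoprotein gene Thy1 went from almost no UMI to clear expression. Tcf21, a transcription factor of fibroblasts in several organs, and Coch, which encodes the extracellular protein cochlin, were nearly lost. With edgeR, 107 of 11563 genes passed an adjusted p of 0.05, with 55 higher and 52 lower, and 2339 had an unadjusted p below 0.05. DESeq2 gave 717 (363 higher and 354 lower).

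Among the rises in stromal-like cells, Vcan was at least 58.8-fold higher (0 UMIs in control, 134.5 CPM with SD 18.7 in stroke, adjusted p = 0.0173). Mmp3, whose product cleaves matrix proteins, was at least 50.6-fold higher (stroke 107 CPM, SD 11.7, adjusted p = 0.0173), and Ahnak2, a large scaffold gene, at least 28.4-fold higher (adjusted p = 0.0320). Ratios of sums were 615 for Thy1 (interval 110 to 24299 from 1 control UMI, adjusted p = 0.0117), 257 for the imprinted RNA H19 (87.8 to 1245), 74.2 for the fibrillar collagen gene Col11a1 (20.5 to 613.5) and 66.4 for the angiotensinogen gene Agt (22.7 to 322). Igf1, a growth factor gene, rose by 5.24 log2 units (SE 0.33, adjusted p = 0.00983), from 14.98 to 571 CPM. Col1a1, the main chain of type I collagen, rose by 3.85 (SE 0.36, adjusted p = 0.0173) and Col4a1 of the basement membrane by 2.43 (SE 0.33, adjusted p = 0.0401).

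Among the falls in stromal-like cells, Tcf21 went from 241 UMIs to 1, an inverse ratio of 2506 (446 to 99400, adjusted p = 0.00783). Coch fell by 6.89 log2 units (SE 0.37, adjusted p = 0.00783), from 516 to 4.36 CPM, and Adh1, an alcohol and retinol dehydrogenase gene, fell by 7.55 (SE 0.59, adjusted p = 0.0117). Trf, which encodes transferrin, fell by 4.30 (SE 0.31, adjusted p = 0.0117), from 1090 to 55.2 CPM. The dipeptidase gene Dpep1 fell by 5.40 (SE 0.33, adjusted p = 0.00983), the phosphatase gene Alpl fell by 4.26 (SE 0.58, adjusted p = 0.0401) and the calcium sensor gene Hpca fell by 5.86 (SE 0.50, adjusted p = 0.0155). Tcf21, Coch, Adh1, Dpep1, Alpl and Hpca were also among the leading genes of the fibroblast-like cluster made of control cells alone. Without that cluster Coch stayed called (-4.46, adjusted p = 0.0241), the calls ended for Dpep1 (-2.00, SE 0.69, adjusted p = 0.162) and Alpl (-1.60, SE 1.09, adjusted p = 0.446), and Tcf21, Adh1 and Hpca had too few UMIs left to be tested.

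Of the genes fixed beforehand, only Col1a1 and Col4a1 passed in stromal-like cells. The pericyte genes had values of -2.07 for Vtn (adjusted p = 0.126), -1.17 for the potassium channel gene Kcnj8 (0.119), -0.96 for its partner Abcc9 (0.226), -1.37 for Cspg4 (0.0755) and -0.88 for Pdgfrb (0.257). Values were 1.07 for Rgs5 (0.232), 2.71 for the smooth muscle actin gene Acta2 (0.108), -0.17 for Pdgfra (0.866), -0.65 for Hic1 (0.291) and 0.27 for tdTomato (0.863), all by edgeR. Mki67, a marker of dividing cells, had 2 control and 151 stroke UMIs, a ratio of 7.26 (1.98 to 60.5, adjusted p = 0.155). Since the classes differed in share, these sums mix a change in make-up with a change within cells.

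The number of calls in stromal-like cells depended on which pools set the spread. With a control left out the spread came from the 2 stroke pools alone, and with a stroke pool left out from the 2 control pools alone. None of the 107 called genes that could be tested changed sign in these fits. Without control 1 only 3 genes passed and without control 2 only 3, all lower, while 882 passed without stroke 1 and 1165 without stroke 2. Over all 18 alternatives Coch stayed called (highest adjusted p = 0.0369), and so did Tcf21 in the 17 that tested it (0.0369). Col1a1 was called in 16 of 18 (highest adjusted p = 0.0944), as were Vcan, Mmp3 and Igf1 (0.0824 for each), and Col4a1 was called in 15 (0.202).

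**Figure D2:**
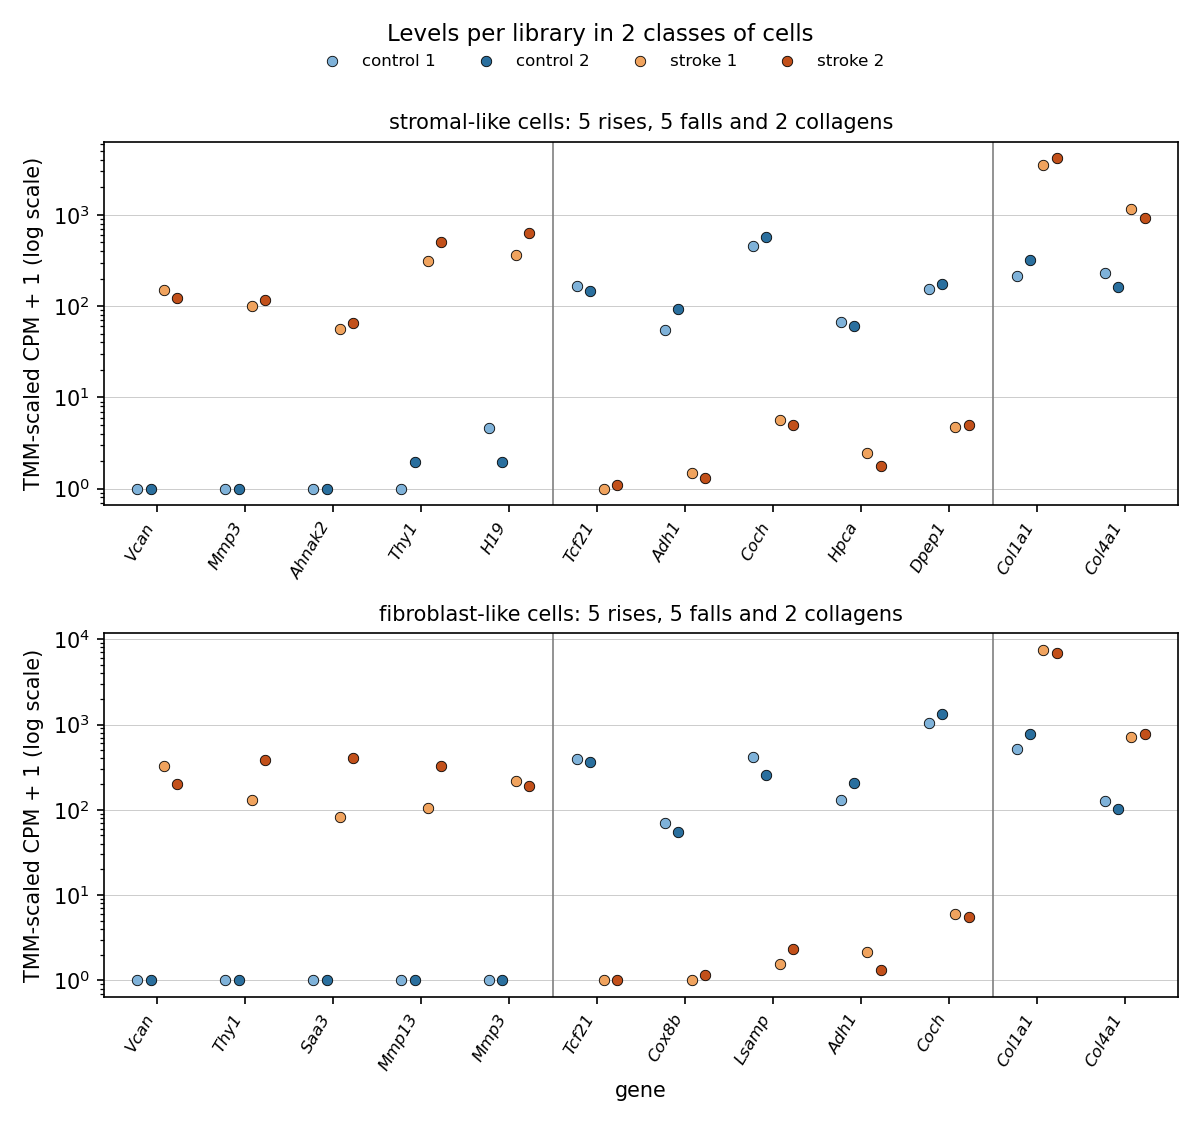
Expression (TMM-scaled CPM + 1, log axis) of the 5 largest rises and 5 largest falls and of Col1a1 and Col4a1, with 1 point per library, in stromal-like cells (top) and fibroblast-like cells (bottom). Coch, at 516 CPM on average in control and 4.36 in stroke stromal-like cells, lies apart in every library.

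Of the lists in stromal-like cells, interstitial collagens had the smallest camera p. Interstitial collagens were higher (15 tested, camera adjusted p = 2.62e-29, and adjusted p = 0.176 with an estimated correlation), with 8 members higher over all genes and 14 adjusted over the list alone, among them Col3a1 (4.70, SE 0.35) and Col6a3 (4.91). Basement membrane genes were higher (15 tested, adjusted p = 8.06e-07, and adjusted p = 0.188 with an estimated correlation), with Col4a1, Col4a2 (2.56) and Col18a1 (2.38) called and 9 higher and 1 lower adjusted over the list alone. Matricellular and scar matrix genes were higher (17 tested, adjusted p = 9.55e-14, and adjusted p = 0.188 with an estimated correlation), with 5 called, among them Fn1 for fibronectin (5.20), Postn for periostin (2.99) and Fbn1 for fibrillin (3.14), and 11 higher and 1 lower adjusted over the list alone. By fry these lists moved on balance upward, with adjusted p = 0.0126 for interstitial collagens and 0.0204 for the other 2. Proteases and their inhibitors were higher (17 tested, adjusted p = 1.36e-10, and adjusted p = 0.188 with an estimated correlation), with Mmp3, Timp1 (5.22) and Adamts4 (ratio 27.5, 7.57 to 227) called and 9 higher and 1 lower adjusted over the list alone.

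Other lists called at the preset correlation in stromal-like cells included the following. Cell cycle genes were higher (27 tested, camera adjusted p = 4.62e-14, and adjusted p = 0.382 with an estimated correlation), where Ube2c alone was called, from 1 to 456 UMIs (ratio 43.8, 7.83 to 1736), against 17 adjusted over the list alone. Ribosomal protein genes were higher (20 tested, adjusted p = 3.76e-13, and adjusted p = 0.382 with an estimated correlation), with 0 called over all genes and 19 adjusted over the list alone. Solute transporters were lower (14 tested, adjusted p = 2.64e-06, and adjusted p = 0.188 with an estimated correlation), with 0 called and 6 lower adjusted over the list alone, among them Slc38a11 (-1.83), Slc13a4 (-2.14) and Slc6a13 (-1.70), and fry did not call this list on balance (adjusted p = 0.0679). Vasoactive receptors and channels were lower (13 tested, median -0.87, adjusted p = 0.0296, and adjusted p = 0.382 with an estimated correlation), with 0 called and 1 lower adjusted over the list alone, and this was the lower list that fry called (adjusted p = 0.0276). Its camera call ended without control 1 (0.126), without stroke 1 (0.0554) and without stroke 2 (0.0920). Pericyte markers were lower (11 tested, adjusted p = 0.000216, and adjusted p = 0.247 with an estimated correlation), with 0 called and 7 lower adjusted over the list alone. Interferon-induced genes were higher (17 tested, adjusted p = 0.000108, and adjusted p = 0.478 with an estimated correlation), with 0 called and 5 higher adjusted over the list alone. Abundant immune RNA, which marks the carrier population, was higher as well (12 tested, median 0.80, adjusted p = 0.0178, and adjusted p = 0.624 with an estimated correlation), with 0 called and 0 adjusted over the list alone. Its adjusted p was 6.6e-19 without control 1, and without control 2, the library without carriers, it pointed downward at 0.423.

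Single members of further lists passed in stromal-like cells. Lox, which cross-links collagen, rose by 2.91 (adjusted p = 0.0271), Pmepa1 of the TGF-beta response by 3.01 (0.0185), the transcription factor gene Osr1 by 2.75 (0.0401), the angiogenic gene Angptl4 by 3.21 (0.0347) and the lipid carrier gene Fabp5 by 4.29 (0.0320). Among chemokine genes Ccl19 fell by 3.53 (adjusted p = 0.0173) and Cxcl14 fell by 4.93 (0.0320). For angiogenic factors the median of members was -0.09 and the mean 0.16, and camera gave an upward adjusted p of 0.397. In all, camera called 19 of 27 lists (17 higher and 2 lower) at the preset correlation and 0 with an estimated one, and fry called 4 on balance (3 higher and 1 lower) and 14 in either direction.

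Which genes differed in fibroblast-like cells? Type I and type III collagen, elastin, fibronectin and metalloprotease genes rose in these cells. Tcf21, Coch and Lsamp, leading genes of the fibroblast-like cluster made of control cells alone, were nearly absent in stroke. Whether cells lost this state or such cells were absent from the dissected area was not tested. Mylk and Des of the contractile apparatus also fell. With edgeR, 269 of 9661 genes passed, with 94 higher and 175 lower, and 1734 had an unadjusted p below 0.05. DESeq2 gave 493.

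Rises in fibroblast-like cells were at least 41.2-fold for Vcan (adjusted p = 0.00953), 59.4-fold for Thy1 (0.0205), 49.4-fold for the collagenase gene Mmp13 (0.0262), 35.4-fold for Mmp3 (0.00742), 59.9-fold for the acute-phase gene Saa3 (0.0464) and 13.8-fold for the zinc transporter gene Slc39a14 (0.0160), each from 0 control UMIs. Ahnak2 was at least 19.9-fold higher (0.0107). H19 had a ratio of 271 (75.1 to 2242, adjusted p = 0.00742). Col1a1 rose by 3.47 (SE 0.38, adjusted p = 0.0104), from 647 to 7204 CPM, and Col4a1 by 2.71 (SE 0.32, adjusted p = 0.0107). Eln, for elastin, rose by 5.62 (SE 0.70, adjusted p = 0.0125), Igf1 by 4.96 (0.00594), Fn1 by 4.98 (0.00953), Mmp14 by 3.30 (0.0200) and Tgfb2, a TGF-beta ligand gene, by 3.07 (0.0340).

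Falls in fibroblast-like cells began with Tcf21, at least 1133-fold lower (233 to 0 UMIs, adjusted p = 0.00372). Coch fell by 7.94 (SE 0.41, adjusted p = 0.00250), Adh1 fell by 8.15 (SE 0.62, 0.00594) and Lsamp, a cell adhesion gene, fell by 8.19 (SE 0.54, 0.00372). Tcf21, Coch, Adh1 and Lsamp were among the leading genes of the cluster of control cells alone. That cluster held 25 of 56 and 26 of 46 control fibroblast-like cells. Without it 78664 of 225366 and 88117 of 358914 fibroblast-like UMIs remained in control 1 and control 2. Its fibroblast markers averaged 0.232 log2 units above all other cells, the lowest such score of a named cluster, with 5 markers raised. The falls of these genes, and other values of this class, can thus mix a change in make-up with a change within cells. Idi1, which encodes an isomerase of isoprenoid synthesis, had an inverse ratio of 243 (78.6 to 1219). Cox8b, a mitochondrial subunit gene, had an inverse ratio of 540 (91.1 to 21889), and Plac9b, a small secreted-protein gene, fell by 6.70 (0.0108). Abcc9 fell by 2.92 (SE 0.40, adjusted p = 0.0178), the myosin kinase gene Mylk fell by 2.63 (0.0125) and the desmin gene Des fell by 2.74 (0.0284). Vtn had a value of -1.84 (0.0618), Kcnj8 -2.15 (0.0815), Rgs5 -1.92 (0.286) and Cspg4 -0.88 (0.643). Not called either were Hic1 (0.12), Pdgfrb (-0.03), Pdgfra (-0.46), tdTomato (0.58) and Acta2 (0.86).

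Among lists in fibroblast-like cells the interstitial collagens again had the smallest camera p. Interstitial collagens were higher (15 tested, camera adjusted p = 2.52e-24, and adjusted p = 0.192 with an estimated correlation), with 10 called and 13 adjusted over the list alone, led by Col3a1 (5.10, from 200 to 6879 CPM). Solute transporters were lower (12 tested, adjusted p = 1.95e-07, and adjusted p = 0.192 with an estimated correlation), with Slc6a13, Slc6a20a and Slc30a10 called and 1 higher and 9 lower adjusted over the list alone. Slc6a13, which takes up GABA and taurine, fell by 1.90, Slc6a20a fell by 2.17 and the manganese exporter gene Slc30a10 fell by 2.67. Contractile genes were lower (9 tested, adjusted p = 0.0258, and adjusted p = 0.573 with an estimated correlation), with 2 called and 1 higher and 3 lower adjusted over the list alone. Cell cycle genes got no call (5 tested, adjusted p = 0.684), with a median of -0.27 and a mean of 1.50. Camera called 15 of 27 lists (12 higher and 3 lower), 0 with an estimated correlation, and fry called 5 on balance and 15 in either direction.

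Without control 1, 132 genes passed in fibroblast-like cells, without control 2 29, without stroke 1 484 and without stroke 2 562. Without the cluster of control cells alone 152 passed, and 91 of the 269 were kept. Vcan, Mmp3, H19, Col3a1, Eln and Igf1 were called in all 16 alternatives, with a highest adjusted p of 0.0499, 0.0445, 0.0308, 0.0341, 0.0484 and 0.0445. Col1a1 was called in 15 (up to 0.0550), and Abcc9 in 14 (up to 0.0970).

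Which genes differed in pericyte-like cells? None passed with edgeR (0 of 5535), while 391 had an unadjusted p below 0.05 and DESeq2 called 29. With the replicate numbers as a block in the edgeR fit 262 passed, though no label states that same-numbered pools share mice. Among interferon-induced genes Ifit1, an antiviral RNA-binding protein gene, had a value of 5.05 (SE 0.60, adjusted p = 0.103), the interferon regulator Irf7 4.30 (0.103) and Rtp4 3.39 (0.103). The chemokine gene Cxcl10, with 0 control UMIs, was at least 35.4-fold higher in the sums (0.103). The pericyte genes had values of Vtn -0.17, Kcnj8 -0.19, Pdgfrb -0.20, Cspg4 -0.38, Abcc9 -0.55 and Rgs5 0.44, and values were 0.45 for tdTomato, -0.84 for Hic1, 2.16 for Acta2, 1.01 for Col1a1 and 1.44 for Col4a1 (adjusted p = 0.201). Stroke 1 supplied only 24 cells, and 103 genes passed without control 1, 65 without control 2, 156 without stroke 1 and 49 without stroke 2.

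Among lists in pericyte-like cells the interferon-induced genes were higher (16 tested, camera adjusted p = 2.22e-49, and adjusted p = 0.287 with an estimated correlation), with 0 called over all genes and all 16 adjusted over the list alone. The cluster with Ifit genes among its leading genes held 2 of 24 pericyte-like cells in stroke 1 and 100 of 366 in stroke 2. Without it 47186 of 59286 and 784511 of 1267370 UMIs remained. The lists were not tested without that cluster, so a rise across the whole class was not shown. Antigen presentation genes were higher (8 tested, adjusted p = 5.37e-06, and adjusted p = 0.313 with an estimated correlation), with 0 called and 4 adjusted over the list alone. Abundant immune RNA, which marks the carrier population, was higher beside them (8 tested, all 8 with values above 0, median 1.16, adjusted p = 0.000132, and adjusted p = 0.390 with an estimated correlation), with 0 called and 1 adjusted over the list alone. Its camera adjusted p was 7.96e-25 without control 1 and 0.985 without control 2, the library without carriers. Basement membrane genes were higher (12 tested, adjusted p = 1.22e-05, and adjusted p = 0.287 with an estimated correlation), with 0 called and 4 adjusted over the list alone. Camera called 17 of 25 lists, all higher, 0 with an estimated correlation, and fry called 0 on balance and 7 in either direction. Without stroke 2 camera called 6.

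Mural-like cells, in which pericyte-like and smooth muscle-like cells were joined, gave 0 of 10027 calls with edgeR, 1696 genes at an unadjusted p below 0.05 and 357 with DESeq2. Values were 2.98 for Acta2 (adjusted p = 0.139), 2.40 for Col4a1 (0.120), 1.38 for Rgs5 (0.179) and -1.72 for Vtn (0.304), and Mki67 was at least 6.25-fold higher from 0 control UMIs (0.153). Pericyte-like cells made up 124 of 183 and 134 of 182 mural-like cells in control and 24 of 350 and 366 of 685 in stroke, so values here also carry a shift between the joined classes. Pericyte markers were lower as a list (11 tested, 1 with a value above 0, median -0.86, camera adjusted p = 0.00721, and adjusted p = 0.551 with an estimated correlation), with 0 called and 1 higher and 2 lower adjusted over the list alone. Contractile genes were higher as a list (11 tested, camera adjusted p = 7.1e-05, and adjusted p = 0.342 with an estimated correlation), with 0 called and 5 adjusted over the list alone. Cell cycle genes were higher as a list (26 tested, adjusted p = 7.91e-24, and adjusted p = 0.342 with an estimated correlation), with 0 called and 21 adjusted over the list alone. Camera called 20 of 27 lists (19 higher and 1 lower), 0 with an estimated correlation, and fry called 0 on balance and 0 in either direction. Without stroke 1, 541 genes passed, without stroke 2 1123, and 0 without control 1 or without control 2.

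Did the stroke effect differ between fibroblast-like and pericyte-like cells? It did for 377 of 7459 genes by the edgeR interaction test (135 with the higher effect in fibroblast-like cells and 242 with the lower), and 1205 had an unadjusted p below 0.05. Col1a1 had the higher effect in fibroblast-like cells by 2.20 (adjusted p = 0.0147), Col4a1 by 1.28 (0.00842), the elastic fibre gene Fbln1 by 4.16 (3.3e-08) and Eln by 3.63 (0.0112). Vtn (-1.65, adjusted p = 1.6e-06), Kcnj8 (-1.96, 0.000178), Abcc9 (-2.37, 2.45e-05), Rgs5 (-2.01, 0.00415) and Trf (-4.73, 2.36e-10) had the lower effect there. No difference was called for tdTomato (0.24, adjusted p = 0.742), Hic1 (0.71, 0.456), Pdgfrb (0.10, 0.922), Pdgfra (1.41, 0.479), Cspg4 (-0.30, 0.880) or Acta2 (-1.34, 0.3). The count was 413 without control 1, 86 without control 2, 451 without stroke 1 and 145 without stroke 2.

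Without control 2 the differences were no longer called for Vtn (-1.51, adjusted p = 0.298), Kcnj8 (-1.54, 0.617), Abcc9 (-1.73, 0.302), Fbln1 (3.69, 0.189) and Rgs5, whose sign was reversed (0.19). The calls of Col1a1 and Eln ended there as well, but control 1, then the only control, had 0 UMIs of either in pericyte-like cells, so no value is given. Col1a1 also had 0 UMIs in pericyte-like cells of stroke 1, so its difference rests on control 2 and stroke 2 on that side. Without stroke 2 the call was lost for Eln (2.75, 0.316) and Col4a1 (1.07, 0.170), and for Col4a1 also without control 1 (1.22, 0.0642) and without control 2 (1.36, 0.582).

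**Figure D3:**
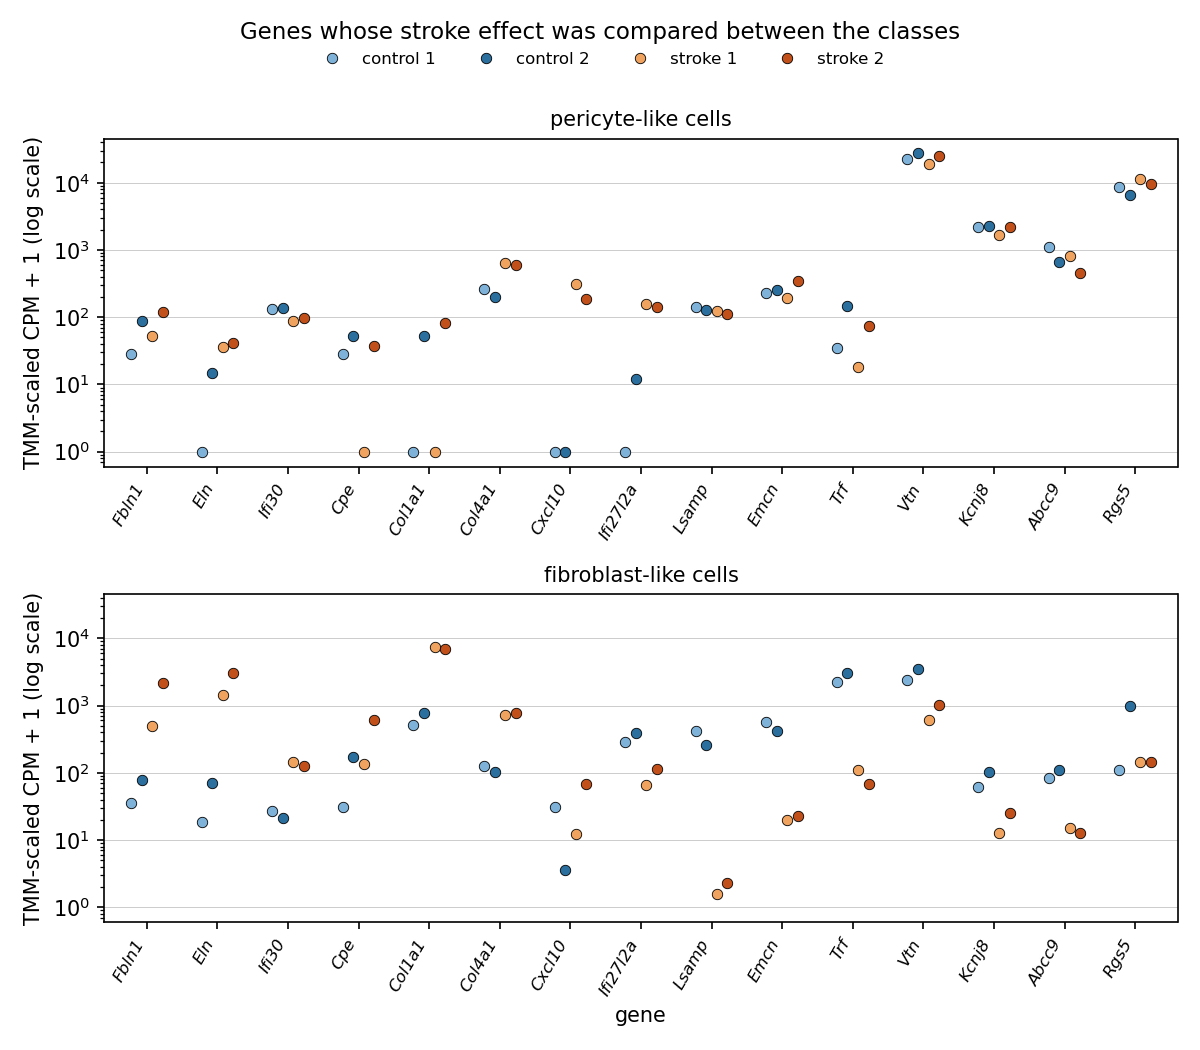
Expression (TMM-scaled CPM + 1, log axis) of genes named for the difference between classes, with 1 point per library, in pericyte-like cells (top) and fibroblast-like cells (bottom). Vtn of pericyte-like cells has an effect of -0.17, while Col1a1 of fibroblast-like cells is higher by 3.47 log2 units.

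Did cells divide more after stroke? At equal depth, cycling cells made up 0 of 154 (at most 1.95%) and 0 of 209 (at most 1.44%) control stromal-like cells, and 3.95% (2.52 to 5.87) and 1.35% (0.771 to 2.18) of those of stroke, a difference of 2.649 points (exact permutation p = 0.333). Shallow cells left out numbered 85, 19, 2 and 0, and the unthinned shares were 0, 0, 11.6 and 4.5%. By class, 22 of 325 and 15 of 319 smooth muscle-like stroke cells cycled, 1 of 234 and 1 of 504 fibroblast-like and 0 of 23 and 0 of 366 pericyte-like cells, and the unthinned shares were 17.2 and 11.9%, 4.70 and 2.78%, and 4.17 and 0.273%. Of these smooth muscle-like cells, 21 and 13 lay in a cluster with Cdc20 and Ccnb1 among its leading genes (32 and 15 cells), which encode regulators of mitosis. That cluster had 7 smooth muscle markers raised and 0 among its leading genes, and it was counted to this class as a whole. With the class given cell by cell from marker genes, 12 of 171 and 15 of 270 smooth muscle cells cycled, 5 of 238 and 1 of 503 fibroblasts and 6 of 173 and 0 of 416 pericytes. For all stromal-like cells a looser rule, a UMI of at least 1 of the 10 genes at equal depth, was also used. It gave mean shares of 2.43% in control and 9.77% in stroke, with 3.90% (1.44 to 8.29) in control 1.

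What did the carrier microglia show? Compared over 1 control and 2 stroke libraries, no gene passed with edgeR (0 of 7615), 1071 had an unadjusted p below 0.05 and DESeq2 called 111. The lipoprotein gene Apoe had a value of 6.20 (SE 0.44, adjusted p = 0.0570), the osteopontin gene Spp1 10.57 (0.0570, from 9 control UMIs) and the lipase gene Lpl 6.19 (0.0570). Genes of resting microglia had P2ry12 -2.07 (0.101), Tmem119 -1.75 (0.132) and Cx3cr1 -1.57 (0.274), and Mki67 had a ratio of 6.22 (1.06 to 252, adjusted p = 0.374). Control is a single library here, so each of these p values rests on the spread between the 2 stroke libraries alone.

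With 1 control library the lists in microglia-like cells describe that library against the 2 of stroke. Damage-associated microglia genes had values toward stroke (19 tested, camera adjusted p = 2.57e-41, and adjusted p = 0.350 with an estimated correlation), with 0 called over all genes and 18 adjusted over the list alone, among them Cst7 (5.59) and Lgals3 (at least 82.3-fold, from 0 control UMIs). Homeostatic microglia genes had values toward control (18 tested, adjusted p = 1.09e-08, and adjusted p = 0.350 with an estimated correlation), with 0 called and 10 lower adjusted over the list alone. Lipid handling genes had values toward stroke (10 tested, adjusted p = 3.99e-17, and adjusted p = 0.350 with an estimated correlation), with 0 called and 6 adjusted over the list alone, including Plin2 (5.11), which coats lipid droplets. Markers of the other sorted population also had values toward stroke: abundant stromal RNA (13 tested, 12 with values above 0, median 3.28, adjusted p = 6.06e-07, and adjusted p = 0.525 with an estimated correlation) had 0 called and 7 higher and 1 lower adjusted over the list alone. Fibroblast markers (8 tested, 7 with values above 0, median 3.58, adjusted p = 5.61e-05, and adjusted p = 0.542 with an estimated correlation) had 0 called and 3 higher adjusted over the list alone, and the 3 interstitial collagens measured had a median of 5.44. Camera called 15 of 21 lists (14 higher and 1 lower), 0 with an estimated correlation, and fry called 0 on balance and 0 in either direction. Microglia-like cells made up 86.2% (81.9 to 89.9), 21.2% (17.2 to 25.8) and 76.5% (72.6 to 80.1) of immune-lineage cells in control 1, stroke 1 and stroke 2 (permutation p = 0.667 over 3 libraries). The difference of -37.37 points became -9.77 without stroke 1 and -64.98 without stroke 2, and lay between -24.29 and -53.62 under other settings. Since defining genes such as P2ry12 differed in value between the groups, these shares are given as values alone.

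**Figure D4:**
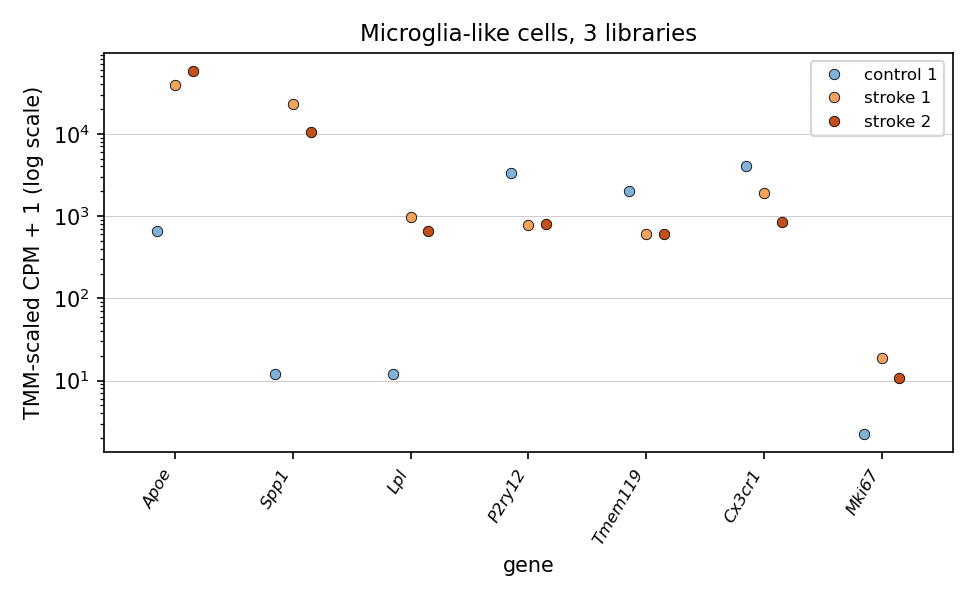
Expression (TMM-scaled CPM + 1, log axis) of 7 genes in microglia-like cells, with 1 point for each of control 1, stroke 1 and stroke 2. Apoe, Spp1 and Lpl are higher in both stroke points (Apoe by 6.20 log2 units), and P2ry12, Tmem119 and Cx3cr1 are lower.

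Positions of the main genes in GRCm38 (mm10) are as follows. Vcan lies on chr13 (89655312 to 89742509), Mmp3 on chr9 (7445822 to 7455975), Thy1 on chr9 (44043384 to 44048579), Igf1 on chr10 (87858265 to 87937042) and Col1a1 on chr11 (94936224 to 94953042). Col4a1 lies on chr8 (11198423 to 11312826), Tcf21 on chr10 (22817281 to 22820174), Coch on chr12 (51593341 to 51605771) and Hic1 on chr11 (75164565 to 75169519). Vtn lies on chr11 (78499091 to 78502324), Kcnj8 on chr6 (142564837 to 142571614), Abcc9 on chr6 (142587862 to 142702315), Rgs5 on chr1 (169655501 to 169695813), Apoe on chr7 (19696109 to 19699188) and Spp1 on chr5 (104435118 to 104441050).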

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

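Every test of an explanation in this part was chosen after the result it addresses had been seen. The results listed first drew attention because the stroke effect differed between fibroblast-like and pericyte-like cells by the edgeR interaction test. The 3 patterns weighed after them are the absence of carrier cells in control 2, the few pericyte-like cells in stroke 1, and the lower pericyte markers of fibroblast-like cells after stroke.

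The effect differed for 377 genes, of which 184 were kept without the cluster of control cells alone. Genes with the higher effect in fibroblast-like cells were Fbln1 (4.16), Eln (3.63), the lysosomal reductase gene Ifi30 (3.00), Tpd52 (2.76), the adaptor gene Grb10 (2.71), the peptide-processing gene Cpe (2.62), the spermidine synthase gene Srm (2.47), Col1a1 (2.20) and Col4a1 (1.28). Palmd, with 2 control UMIs in fibroblast-like cells, had an adjusted p of 0.00815. Genes with the lower effect in fibroblast-like cells were Lsamp (-7.76), the interferon-induced gene Ifi27l2a (-6.10, from 4.34 in pericyte-like and -1.92 in fibroblast-like cells), the neurturin receptor gene Gfra2 (-5.09), Adgrf5 (-5.00), the sialomucin gene Emcn (-4.83), Trf (-4.73) and Rasgrp2 (-4.55). Of the pericyte genes, Abcc9 (-2.37), Rgs5 (-2.01), Kcnj8 (-1.96) and Vtn (-1.65) had the lower effect there. Cxcl10, with 0 control UMIs in pericyte-like cells, had an adjusted p of 0.032. Without the cluster of control cells alone the difference of Emcn turned to 1.50 (adjusted p = 0.653), and Lsamp (-2.00, adjusted p = 0.702), Ifi27l2a (-1.90, adjusted p = 0.512) and Col4a1 (0.51, adjusted p = 0.594) were no longer called.

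No immune-lineage cell was found among 251 cells of control 2, at most 1.20%, against 56.1, 38.6 and 30.1% in control 1, stroke 1 and stroke 2. If carriers had been captured and then removed from the matrix, their free RNA would remain in the stromal-like cells. The share of abundant immune RNA there was 0.0932 of that in control 1 and 0.143 of the lowest share among the other libraries. These values argue against removal as the whole cause and fit few or no carriers in the loaded suspension. They do not exclude removal, since this RNA did not follow the share of immune-lineage cells. It stood at 0.0780, 0.0509 and 0.0836% in control 1, stroke 1 and stroke 2. No biological explanation was tested, since the sort and not the tissue set the number of carriers.

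Pericyte-like cells made up 4.11% of the stromal-like cells of stroke 1 and 30.8% of those of stroke 2. A minimum UMI count of the barcodes was left open. Held to the stroke 1 minimum of 1464 UMIs, the control kept a share of at least 45.6% pericyte-like cells. This could not exclude it, since the classes differed more in depth in stroke 1. Median UMIs of pericyte-like, smooth muscle-like and fibroblast-like cells were 2096, 6492 and 8690 there, against 1582, 1685 and 3625 in control 1. More uninjured tissue in the stroke 2 pool was left open: the main control cluster, led by P2ry12 and Cx3cr1, made up 3.05% of its microglia-like cells and 28.2% of those in stroke 1, but with the cluster led by Ccl12, which also has P2ry12 among its leading genes, the shares were 24.4% (20.3 to 29.0) and 34.6% (24.2 to 46.2). The share of pericyte-like and smooth muscle-like cells together differed by only 2.32 points between the stroke libraries, against 26.7 points for pericyte-like cells alone, which is consistent with mural cells of stroke 1 having been placed in the smooth muscle-like class. A biological change of pericytes toward contractile gene expression would give the same shares, and the 2 were not told apart.

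Vtn, Kcnj8 and Abcc9 were lower in fibroblast-like cells of stroke, with Abcc9 alone called, and Rgs5 was set aside after it was seen to be high in control 2 alone. Free pericyte RNA in the control libraries would add all pericyte markers in equal proportion. Their ratios between the 2 classes spread by at least 3.57-fold in either control library. The 9.36-fold spread of control 1 rests on Cspg4 (1.28%, 0.0257 to 9.15), but Rgs5 was also low there (1.43%, 0.882 to 2.22). In control 1 free RNA was thus excluded as the whole cause for Vtn (12.0%) and Abcc9 (8.51%). In control 2, with Vtn at 15.1% and Abcc9 at 19.5%, only Kcnj8 (5.47%, 3.65 to 7.98) lay apart below them. Rgs5 (17.45%, 15.1 to 20.1) lay with them there, and the interval of Cspg4 (7.69%, 3.13 to 16.7) overlapped that of Vtn. An exclusion in control 2 would rest on Kcnj8 alone. For Kcnj8 (3.17 and 5.47%), among the lower ratios, it was not excluded. Without the cluster of control cells alone the median of the 3 was -2.47, which excluded that cluster as the whole cause. In that fit Abcc9 went from -2.92 (SE 0.40, adjusted p = 0.0178) to -2.47 (SE 0.55, adjusted p = 0.0771) and its call ended with the larger SE, while Vtn stood at -3.31 (SE 0.48, adjusted p = 0.0280) and Kcnj8 at -2.31 (SE 0.59, adjusted p = 0.107). Stroke against the contralateral hemisphere remains as an explanation, together with the dissection of a smaller region, and without control 2 the differences from pericyte-like cells kept their sign (-1.51 for Vtn, -1.54 for Kcnj8 and -1.73 for Abcc9) but were no longer called.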

How the results depend on the processing

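The settings without a cluster, with equal cells per class and library, the mural-like class and the microglia-like fit were chosen after the results were seen. For the genes named in the text 1356 values kept direction and side of the threshold, 103 passed only in the alternative, 86 no longer passed and 33 changed sign. Counts of genes in stromal-like cells (107) became 1543 with no filter, 717 with DESeq2 and 70 with equal cells per class and library, where fewer cells were used. Counts in pericyte-like cells (0) became 171 with no filter and 29 with DESeq2. In fibroblast-like cells (269) they became 1140 with no filter, 493 with DESeq2 and 152 without the cluster of control cells alone. In mural-like cells (0) they became 2 with DESeq2 size factors, 1066 with no filter and 357 with DESeq2. In microglia-like cells (0) they became 13 with DESeq2 size factors, 596 with no filter, 111 with DESeq2, 45 with at least 1000 UMIs per cell, 1 at Leiden resolution 0.5, 38 at 2.0 and 21 with equal cells per library. With no filter the median log2 fold change of all genes in stromal-like cells moved to 0.16, and beyond this the cause was not tested. Leaving out each library in turn gave 3 to 1165 genes in stromal-like, 49 to 156 in pericyte-like, 29 to 562 in fibroblast-like and 0 to 1123 in mural-like cells, and 86 to 451 for the difference between classes. A group left with 1 library was assumed there to vary like the other group. Lists called in stromal-like cells numbered 0 with an estimated correlation and 4 by fry (14 in either direction), and in microglia-like cells 0 with an estimated correlation, 0 by fry and 0 by fry in either direction. Of the called genes, 70 of 107 were kept in stromal-like, 91 of 269 in fibroblast-like cells and 184 of 377 for the difference without the cluster of control cells alone.

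Signs changed without the cluster of control cells alone for Pdgfra in stromal-like cells (0.21), for Hic1 (-0.25) and Pdgfrb (0.03) in fibroblast-like cells, and for the difference between classes of Emcn (1.50) and Acta2 (0.87). Signs also changed for Vtn in pericyte-like cells without the cluster with Ifit genes among its leading genes (0.02) and for Pdgfrb in fibroblast-like cells with no filter (0.08). The cause was not tested, and apart from Emcn none of these genes had been called. Leaving out each library in turn gave, in stromal-like cells, -0.62 to 0.91 for tdTomato and -0.56 to 0.39 for Pdgfra. In pericyte-like cells it gave -0.80 to 1.16 for tdTomato, -0.59 to 0.35 for Pdgfrb, -0.42 to 0.02 for Kcnj8 and -0.40 to 0.05 for Vtn. In fibroblast-like cells it gave -0.31 to 1.24 for tdTomato, -0.20 to 0.39 for Hic1, -0.34 to 0.24 for Pdgfrb, -0.90 to 0.16 for Pdgfra, -1.62 to 1.07 for Cspg4 and -2.76 to 0.42 for Rgs5. In mural-like cells it gave -0.65 to 1.00 for tdTomato. For the difference between classes the ranges were -0.20 to 0.42 for Pdgfrb, -1.65 to 1.58 for Cspg4, -3.37 to 0.19 for Rgs5 and -2.88 to 1.99 for Acta2, where Cspg4 and Acta2 had 1 UMI each in fibroblast-like cells of control 1. Fits over 0 counts gave -1.40 to 3.85 for Eln, -6.81 to 5.74 for Pdgfra and -5.75 to 10.12 for Col1a1. Pericyte-like cells of control 1 had 0 UMIs of all 3 genes, and those of stroke 1 had 0 of Pdgfra and Col1a1, so these limits and the turned signs do not measure a difference.

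The libraries share replicate numbers. The controls are hemispheres contralateral to a stroke, and the labels do not state whether same-numbered pools share mice. With those numbers as a replicate block, the counts were 2714 in stromal-like, 262 in pericyte-like, 1823 in fibroblast-like and 995 in mural-like cells. Deviations of same-numbered libraries correlated at 0.66, 0.40, 0.57 and 0.57 in these classes, and with 2 pairs this does not show that mice were shared. Some variation did follow the number. In pericyte-like cells tdTomato stood at 1951, 4439, 1973 and 6906 CPM in control 1, control 2, stroke 1 and stroke 2, and the cluster led by Car4 held 3, 127, 2 and 265 cells. The fits without a block leave such variation in the spread between pools, and its source was not tested.

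Not run were a fit of macrophage-like cells, which had under 20 cells in both control libraries at every setting, the difference between stromal-like and microglia-like cells, the block and the leave-one-out fits for microglia-like cells, and the microglia-like fit on 4 libraries, since control 2 held none. Depth limits the control libraries most: the smallest stromal-like cells had 499, 779, 1464 and 2292 UMIs.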

Other observations

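The test of an explanation in this part was chosen after the result it addresses had been seen. Smooth muscle-like cells of stroke carried more Rgs5 and Acta2 RNA and less Vtn RNA than those of control, given here as levels without a test. Rgs5, a regulator of G-protein signalling in mural cells, stood at 5570, 7928, 18712 and 14367 CPM in control 1, control 2, stroke 1 and stroke 2. Acta2 stood at 226, 1468, 3192 and 1980 CPM and the smooth muscle myosin gene Myh11 at 37.6, 51.8, 137 and 66.4 CPM. Tagln, another contractile gene, was highest in control 2, at 480, 1342, 810 and 642 CPM. Vtn was lower in stroke, at 11328, 9443, 1339 and 2277 CPM, and so was Kcnj8, at 1308, 1152, 555 and 926 CPM, while Abcc9 stood at 273, 259, 395 and 284 CPM. Defining genes of this class thus differed in level between the groups, and its 2 largest clusters were nearly separate between the stroke libraries (282 of 287 cells from stroke 1, 284 of 286 from stroke 2).

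A pericyte-like cluster with Ifit3, Ifit1 and Iigp1 among its leading genes held 1, 0, 2 and 100 cells, while Cxcl10 of pericyte-like cells stood at 314 CPM in stroke 1 and 185 in stroke 2. In microglia-like cells the growth factor gene Igf1 had a ratio of 280 (50.1 to 11050, adjusted p = 0.0570 by edgeR), the lipid carrier gene Fabp5 a ratio of 119 (40.7 to 577, adjusted p = 0.0570) and the cytokine gene Il1b a ratio of 65.0 (11.6 to 2572, adjusted p = 0.0688), none of them called. Interferon-induced genes had values toward stroke there as a list (16 tested, camera adjusted p = 2.22e-20, and adjusted p = 0.350 with an estimated correlation), with 0 called over all genes and 13 adjusted over the list alone. Microglia-like cells of stroke were spread over a cluster led by Apoc1 and Cst7 (36 and 284 cells in stroke 1 and stroke 2), a cluster led by P2ry12 and Cx3cr1 (22 and 12 cells), a cluster led by Pbk and Birc5 (15 and 13 cells) and a cluster led by Ccl12, Adgrg1 and P2ry12 (5 and 84 cells). Of the 263 in control 1, 259 lay in the cluster led by P2ry12 and Cx3cr1.

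A higher frequency of division in smooth muscle-like than in fibroblast-like cells after stroke was taken up as a hypothesis. At equal depth 6.77 and 4.70% of smooth muscle-like cells cycled in stroke 1 and stroke 2, against 0.427 and 0.198% of fibroblast-like cells (unthinned 17.2 and 11.9% against 4.70 and 2.78%), and the larger Fisher exact p was 0.000107. With the class given cell by cell the shares were 7.02 and 5.56% against 2.10 and 0.199%, and the larger p was 0.0214, so the order held in both libraries. These p values count cells within a pool and not pools. The line toward pericytes is open, since cell by cell only 149 of 293 smooth muscle-like cells of stroke 1 outside the cycling cluster kept that class (234 of 304 in stroke 2).

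Cycling microglia-like cells numbered 0 of 246 in control 1 (at most 1.22%), 13 of 77 in stroke 1 (16.9%) and 14 of 393 in stroke 2 (3.56%) at equal depth, with 17, 1 and 0 shallow cells left out and a permutation p of 0.667 over 3 libraries. Unthinned shares were 0.380, 21.8 and 11.45%. Of the cycling cells 12 and 11 lay in a cluster led by Pbk and Birc5 (15 and 13 cells), and the stroke shares were 1.61 and 1.31% at Leiden resolution 0.5, 21.0 and 5.67% at 2.0 and 8.92 and 3.34% with no doublet removal. Dendritic-like cells numbered 3, 0, 76 and 20, T cell-like cells 9, 0, 47 and 30, and B cell-like cells 17, 0, 4 and 0.

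The bulk workbook carries a note of 2 brains, while the protocol in the labels speaks of 4 mice. It holds no tdTomato entry, 309 entries at 0 and 8041 at 0.001. Emcn stood at 310 FPKM in that pool, Coch at 277, Abcc9 at 266, Col1a1 at 256 and Tcf21 at 146.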
